A study of Zea mays with 12 samples.

How the data were processed

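RNA-seq was made from 2 tissues of wild-type maize kernels (inbred W22), the basal endosperm transfer layer (BETL) and the maternal transfer zone (MATZ), at 8, 14 and 20 days after pollination (DAP), with 2 libraries in each of 6 groups. Samples were grouped by tissue and age as the labels give them. The authors deposited 1 table of FPKM values (fragments per kilobase of transcript per mapped fragments, scaled to a common library size), with 1 column per library, per the file headers. TopHat2, Bowtie2 and Cufflinks are named per the submitters' processing notes, and their versions, their settings, the genome build and the annotation release are not given in the sources used here. Coordinates are those of the deposited table.

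FPKM values were used as deposited, without rescaling. Of 39423 gene models, 10484 were at 0 in all 12 libraries, and the 24213 with FPKM of at least 1 in at least 2 libraries were tested. Values were put on the log2(FPKM + 1) scale, so fold changes of low genes are understated. Names came from a RefSeq gene table of the assembly Zm-B73-REFERENCE-NAM-5.0, used for names alone: 18770 of the 39423 IDs matched, 16018 of those tested, 2233 of which have a descriptive name, and 520 IDs matched more than 1 record. FPKM splits or drops reads shared by near-identical genes in ways not stated, so members of the betl, meg, esr and zein families are uncertain. The reference holds symbols and synonyms without descriptions, so what a named gene encodes was stated from general knowledge of its name and was not checked against sequence.

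Depth per library is not stated. Within each library, low values of genes spanning at most 3000 bp were compared with whole multiples of a step over the gene span, and 19.0% to 45.3% of them lay within 0.5% of a step, against 1.18% to 1.93% on shifted steps. From 1 step or 2 steps per library, 1 fragment per step gives 94191 to 602344 fragments per library, which is an inference and not a count, and no count test was run.

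Each comparison was tested with limma 3.58.1 in R 4.3.3 (lmFit, contrasts.fit and eBayes with a mean trend) on all 12 libraries in one fit with 6 group means, which leaves 6 residual degrees of freedom (prior degrees of freedom 3.79). P-values were adjusted by Benjamini-Hochberg over the tested genes, and genes with adjusted p under 0.05 were called. The 9 comparisons were BETL against MATZ at each of 3 ages, each age against the one before in each tissue (4), and the difference between the tissues in each of these changes (2). Signed log2 values are BETL minus MATZ, or later minus earlier. Overlaps of calls between comparisons with no shared library are given beside n1 × n2 / N. That number takes calls as independent, while all comparisons share 1 spread per gene, so it is no null value. Tables and figures used Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.

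The design, the rule for named genes, 31 gene lists and the settings to vary were fixed before the data were examined. Lists were matched by symbol or synonym, genes matched by a wrong sense of the pattern were taken out by name (25 from the vascular list and 1 each from 8 others), and 28 lists with at least 3 tested members were tested by camera with a preset correlation of 0.01, adjusted over the lists of a comparison. SWEET sugar exporters (0 members), vascular and phloem markers (1, sut1) and amino acid transporters (2) were not tested. The tested lists were basal endosperm, zein, starch, aleurone, embryo and embryo surrounding region, photosynthesis, MADS-box, invertase, sucrose synthase, sugar transporter, mineral transporter, aquaporin, proton pump, auxin, cytokinin, gibberellin, abscisic acid, ethylene, cell cycle, cell wall, lignin, flavonoid, cell death, defense, lipid transfer, heat shock, hypoxia and ribosomal protein genes. The anchor sweet4c matched no ID, the symbol of the anchor mrp1 matched only a transporter gene of the same name, which was taken out, and tcrr-1 was missed by its list's pattern.

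Named genes were, per tissue or age comparison, the 8 with the largest change in each direction among called genes with a descriptive name, mean FPKM of at least 10 in the higher group and groups that do not overlap, up to 4 members with the highest mean from each list, and fixed anchors (mn1, betl1, bap2, meg1, sh1, sus1, sh2, bt2, o2 and others). For differences of changes they were 5 in each direction. This gave 236 genes, of which the text gives those with the clearest values. Other members of short counts, and unnamed abundant transcripts, were named after their values were seen. Of the list calls counted in the text, 1 is not reported here.

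The settings to vary were pseudocounts of 0.1 and 5, no filter, FPKM of at least 5, median-of-ratios scaling, quantile normalization, a replicate block, a fit on the compared groups alone, no mean trend, camera with an estimated correlation, and leaving out each library. Library weights, a mean FPKM of at least 20 and a fit without the 8 DAP libraries were added later. The test was run on simulated data before the real comparisons, with 200 genes changed in 1 group and 24969 tested for BETL 8 DAP, 24925 for BETL 20 DAP and 24959 for MATZ 20 DAP. Gene means and inferred depths were taken from the deposited values. A transcript length of 1500 bp and a lognormal SD of 0.2 were assumed for all genes and groups. With BETL 8 DAP changed, BETL against MATZ at 8 DAP recovered 0% of 2-fold, 22.4% of 4-fold and 43.9% of 8-fold changes, and 14 against 8 DAP in BETL 0%, 16.4% and 39.4%. With BETL 20 DAP changed, the tissue comparison at 20 DAP recovered 0%, 14.9% and 42.4%, and 20 against 14 DAP in BETL 0%, 8.96% and 45.5%. With MATZ 20 DAP changed, the tissue comparison recovered 1.49%, 14.9% and 31.8%, and 20 against 14 DAP in MATZ 0%, 16.4% and 40.9%. A gene that was not called may therefore still differ. At most 1 unchanged gene was called per comparison and direction. These rates hold for equal spread in all groups. The real groups differed in spread, as given below, so the rates need not hold for them.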

Results

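RNA was sequenced from a pair of facing tissues at the base of the maize kernel, in the inbred line W22. The basal endosperm transfer layer (BETL) is the outermost endosperm next to the mother plant, and its cells take up sugars, amino acids and minerals. The maternal transfer zone (MATZ) is the maternal tissue on the other side, through which these nutrients leave the plant. Pieces of both tissues were dissected from frozen kernels of field plants at 8, 14 and 20 days after pollination (DAP), which gave 6 groups of 2 libraries and 12 libraries in all. The labels do not say that the 2 libraries of a group came from separate plants or ears, so the spread between them may be technical. P-values use 1 spread per gene pooled over the 6 groups, although groups differed in spread. At 100 FPKM or more the replicate SD (log2) was 0.218 in BETL and 0.651 in MATZ at 20 DAP. Standard errors may thus be too small for the noisier groups and too large for BETL at 20 DAP.

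The table lists FPKM values for 39423 gene models, of which 10484 were at 0 in each of the 12 libraries and 24213 passed the filter for testing. Column totals ran from 731024 to 987477 FPKM, and read counts are not part of the values used here. Low values fell on regular steps, and if 1 step is 1 fragment (an inference from the values), the fragments per library can be estimated. They came to about 122717 and 223197 in BETL at 8 DAP, 128145 and 380899 at 14 DAP and 602344 and 492884 at 20 DAP. The same reading gave 295079 and 162054 in MATZ at 8 DAP, 191063 and 115981 at 14 DAP and 257059 and 94191 at 20 DAP. In libraries with 2 steps the number is the mean of 2 estimates that differ. Their steps were 6358 and 10099 (FPKM times bp) in BETL 14 DAP replicate 1, so the numbers are rough. Genes above 0 ranged from 12609 in BETL 8 DAP replicate 1 to 21309 in BETL 20 DAP replicate 1. Of the genes at 10 FPKM or more in one library of a group, 11.9%, 6.54% and 0.557% were listed at 0 in the other in BETL at 8, 14 and 20 DAP. In MATZ the shares were 8.37%, 10.3% and 10.8%, so a 0 is given below only as a listed value. Levels below are mean ± SD in FPKM (n = 2 libraries), and log2 fold changes, given ± SE, are on the log2(FPKM + 1) scale, which understates the change of low genes.

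Across genes, log2(FPKM + 1) of the 2 libraries of a group correlated with r = 0.789 in BETL at 8 DAP, 0.804 at 14 DAP and 0.912 at 20 DAP. In MATZ r was 0.805, 0.794 and 0.791 (genes are not independent replicates). The 10 most abundant genes held 31.8% and 33.4% of all FPKM in BETL at 8 DAP, 25.4% and 24.8% at 14 DAP and 35.9% and 37.3% at 20 DAP. In MATZ they held 26.3% and 28.0% at 8 DAP, 8.54% and 8.69% at 14 DAP and 6.95% and 6.94% at 20 DAP.

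**Figure D1:**
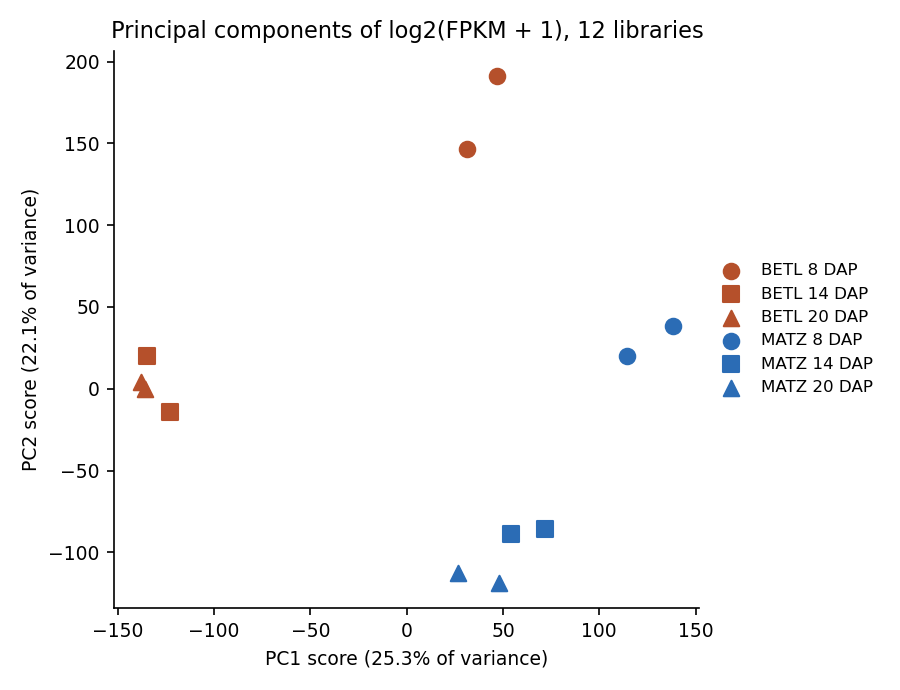
Principal components of log2(FPKM + 1) over 24213 genes, with 1 point per library, component 1 (25.3% of the variance) on the horizontal axis and component 2 (22.1%) on the vertical axis. In each tissue the libraries at 8 DAP lie apart from those at 14 and 20 DAP, which lie nearer each other.

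BETL was compared with MATZ at 8 DAP to ask which transcripts set the endosperm transfer cells apart from the maternal tissue facing them early in grain filling. The BURP domain gene BURP7 and genes named for the basal endosperm were far more abundant in BETL. BURP7 (GRMZM2G032145; chromosome 7, 6570606 to 6574556) stood at 9998 ± 1532 in BETL and 44.8 ± 26.7 in MATZ (SD, n = 2). Levels of bap2 (GRMZM2G152655; chromosome 4, 34264143 to 34265135) were 13024 ± 2367 and 435 ± 7.91, and those of betl-9 (GRMZM2G087413) 6842 ± 1319 and 191 ± 73.7. The cell wall invertase gene mn1 (GRMZM2G119689; chromosome 2, 56806976 to 56810257), whose enzyme splits sucrose as it enters the kernel, stood at 6738 ± 689 against 1114 ± 60.2, a 6.05-fold difference. In the other direction, a chitinase gene (GRMZM2G453805; chromosome 3, 212009199 to 212010553) stood at 1350.5 ± 74.1 in MATZ and 7.67 ± 6.75 in BETL. The plasma membrane aquaporin gene pip2b (GRMZM2G092125; chromosome 2, 168551300 to 168554811) was at 5808 ± 148 and 2481 ± 55.2.

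Of the 15 members of the BETL and basal endosperm list, 14 were higher in BETL at 8 DAP, and 14 adjusted over the list alone, with a median log2 difference of 5.05 (limma camera adjusted p = 1.25e-28). Among them betl3 was at 6782 ± 872 against 378 ± 239 and betl1c at 1719 ± 69.7 against 85.3 ± 103. Also higher in BETL were tcrr-1, a response regulator gene of transfer cells, at 119 ± 5.38 against 0 in both MATZ libraries, and the endosperm gene fl3 at 604 ± 55.9 against 7.86 ± 3.87. The dehydroascorbate reductase gene dhar2 was at 415 ± 40.01 against 5.06 and 0 in the 2 MATZ libraries. Of 14 genes of the embryo and its surrounding endosperm, 3 were higher in BETL, and 4 adjusted over the list alone (median 0.73, mean 1.89, adjusted p = 0.000125). They were esr-6, esr2 at 512 ± 128 against 8.45 ± 3.98, and esr1 at 134 ± 32.9 against 0 in both MATZ libraries. Reads of betl, meg, esr and zein genes may be split between near-identical copies, so levels of single members are uncertain.

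In MATZ, 7 of 28 MADS-box genes were higher, and 9 adjusted over the list alone (median log2 difference −1.52, adjusted p = 0.00025). MADS4 (GRMZM2G097059; chromosome 7, 136261560 to 136272782) was at 462 ± 42.4 against 104 ± 16.5 and zmm6 at 445 ± 2.65 against 89.1 ± 22.1. Of the 3 chitinase genes of the defense list, 2 were higher in MATZ, and 2 adjusted over the list alone (median −2.07, adjusted p = 0.00644). The list had adjusted p = 0.108 with an estimated correlation, and 0.11 without MATZ 8 DAP replicate 2. Single genes higher in MATZ were the aquaporin genes pip2e (402 ± 3.33 against 147 ± 2.98) and PIP1-1 (292 ± 39.6 against 46.4 ± 29.3) and the xyloglucan endotransglycosylase gene xet1 (761 ± 56.02 against 148 ± 78.8). So were the proton pump gene mha2 (168 ± 24.9 against 65.8 ± 2.33; adjusted p = 0.00727, but 0.057 with quantile normalization), the auxin carrier gene AUX3 (305 ± 8.45 against 87.9 ± 1.25) and the ethylene synthesis gene acco20 (55.5 ± 3.84 against 10.9 ± 0.111). The autophagy gene Atg8d was at 262 ± 19.1 against 91.1 ± 15.8, and the thiamine synthesis gene thi1 at 19.3 ± 1.89 against 0 in both BETL libraries. PPCK3, a kinase gene of PEP carboxylase, was at 60.5 ± 21.2 against 0 and 3.54 in the 2 BETL libraries.

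The sucrose synthase gene sus1 was higher in BETL (25.5 ± 2.34 against 1.82 ± 0.7396). The sucrose transporter gene sut1 was too (65.0 ± 2.76 against 13.7 ± 10.4; adjusted p = 0.0136, but 0.0707 without BETL 8 DAP replicate 1). The invertase gene incw1 was higher in MATZ (45.4 ± 8.41 against 6.78 ± 6.34; adjusted p = 0.0155, but up to 0.101 without MATZ 8 DAP replicate 1 or 2). Zein storage protein genes were still low at this age: gz27 stood at 28.7 ± 4.23 in BETL and 7.14 ± 3.54 in MATZ, and bz15 at 0 in both BETL libraries and at 7.104 and 27.9 in the MATZ libraries.

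By limma, 1807 genes differed between BETL and MATZ at 8 DAP, 522 higher and 1285 lower in BETL, of which 457 and 900 by at least 4-fold. BURP7 had a log2 difference of 7.90 ± 0.34 (adjusted p = 1.57e-06), and mn1 of 2.59 ± 0.18 (adjusted p = 2.99e-05). The chitinase gene GRMZM2G453805 had −7.54 ± 0.74 (adjusted p = 0.000284) and pip2b −1.23 ± 0.17 (adjusted p = 0.0029). The median log2 difference of all genes was −0.40, so that the split depended on scaling: it was 715 higher and 1157 lower with median-of-ratios scaling (median −0.21) and 743 and 877 with quantile normalization (median 0.01). Without BETL 8 DAP replicate 1 the count was 1029, and without MATZ 8 DAP replicate 2 it was 1147.

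**Figure D2:**
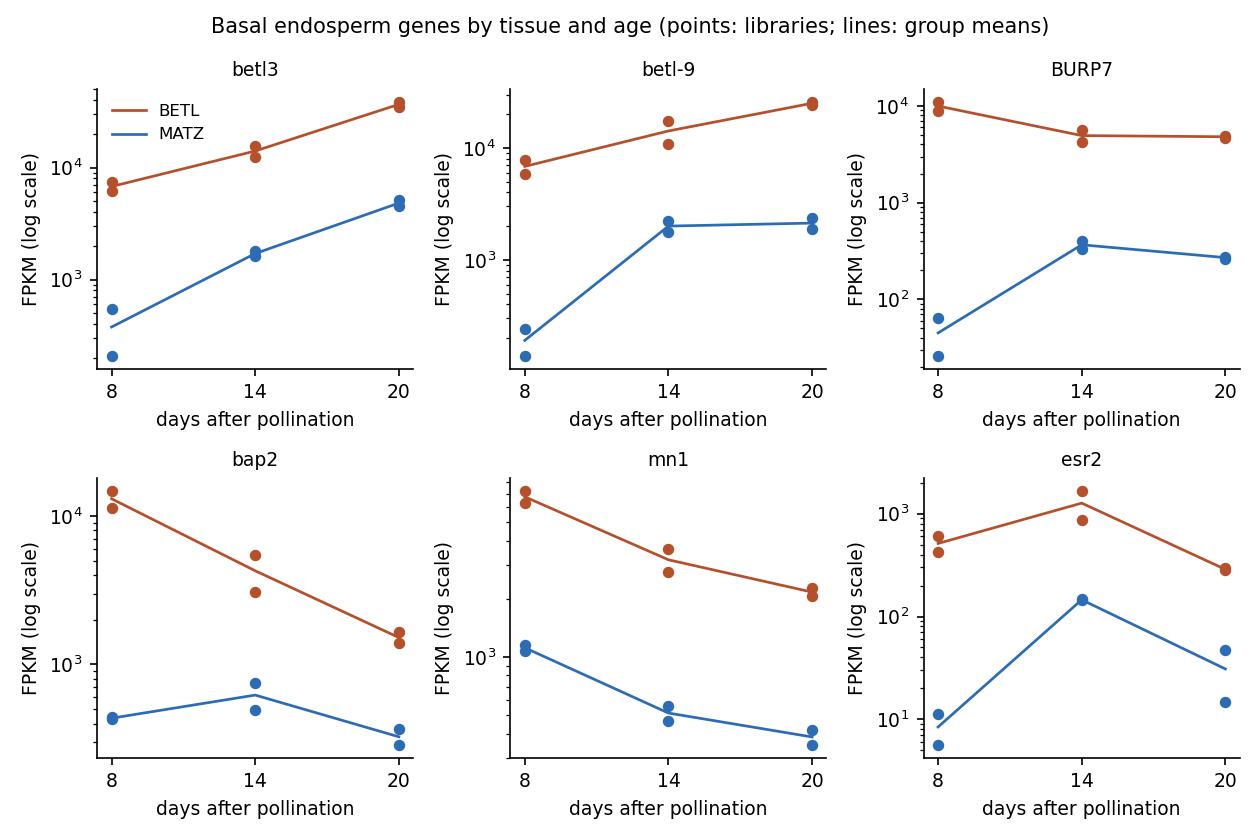
FPKM (log axis) of betl3, betl-9, BURP7, bap2, mn1 and esr2 in BETL and MATZ against age in DAP; points are libraries and lines join the group means. Each gene was called higher in BETL at 8, 14 and 20 DAP, under each scaling tried except that BURP7 was rescaled at 8 DAP alone; bap2 stood at 13024 ± 2367 in BETL at 8 DAP and 1517 ± 181 at 20 DAP.

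The 14 DAP comparison of BETL with MATZ asked the same of the main filling stage. BETL again held most of the transfer cell transcripts, at 14202 ± 4583 FPKM for betl-9 against 2004 ± 322 in MATZ (SD, n = 2) and 14082 ± 2192 for betl3 against 1709.9 ± 105. A further marker, betl10 (GRMZM2G091445; chromosome 3, 155381664 to 155382256), was at 6125 ± 827 against 712 ± 102. The invertase gene mn1 was at 3179 ± 616 against 511 ± 67.2, 6.22-fold. MATZ held more of aquaporin gene pip2b (6395 ± 613 against 903 ± 237, 7.08-fold), of xet1 (3391 ± 142 against 430.2 ± 47.1) and of ccp1, a cysteine protease gene (2332 ± 122 against 379.7 ± 44.98).

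Of the 15 BETL and basal endosperm genes, 11 were higher in BETL at 14 DAP, and 12 adjusted over the list alone (median 2.90, adjusted p = 6.63e-11). The embryo and embryo surrounding list had 3 of 14 higher, and 5 adjusted over the list alone (median 2.10, adjusted p = 0.00479). They were glb1, ole1 and esr2, the last at 1264 ± 558 against 145 ± 2.94 (adjusted p = 0.00705, but 0.0504 without BETL 14 DAP replicate 2). That list had adjusted p = 0.0513 with an estimated correlation, and its call was lost without BETL 14 DAP replicate 2 or MATZ 14 DAP replicate 1 (adjusted p up to 0.0578). Expansin gene expA4 was at 149 ± 16.8 in BETL and at 4.495 and 0 in the MATZ libraries. The male sterility gene ms8 was at 47.5 ± 12.97 against 0 in both MATZ libraries, and COR413-TM1 at 27.3 ± 10.1 against 0 in both.

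MATZ was higher for 10 of 28 MADS-box genes, and for 12 adjusted over the list alone with 1 the other way (median −2.33, adjusted p = 5.99e-09). They included MADS4 (859 ± 42.05 against 113 ± 9.74), zmm27 (514 ± 43.2 against 73.2 ± 28.3) and zag2 (407 ± 59.2 against 61.8 ± 25.3), a gene of ovule development. Of 23 aquaporin genes, 6 were higher in MATZ and 1, tip3a, in BETL, and 8 and 2 adjusted over the list alone (median −0.27, adjusted p = 0.00292). Those in MATZ included pip2e (554 ± 14.6 against 92.8 ± 18.6) and PIP1-1 (308 ± 93.5 against 27.7 ± 2.91). Of 23 cytokinin genes, 3 were higher in MATZ and 1, cko1, in BETL, and 8 and 1 adjusted over the list alone (median −1.03, adjusted p = 0.00292). They were the cytokinin oxidase gene CKX4 (905 ± 35.3 against 139 ± 22.99) and the response regulator genes RR6 and RR9. Of 10 lignin and secondary wall genes, 2 were higher in MATZ, and 2 adjusted over the list alone (median −1.84, adjusted p = 0.00292). These were the laccase genes LAC1 (79.8 ± 7.43 against 13.2 ± 7.05) and Laccase-13 (GRMZM5G814718; 102 ± 4.87 against 9.63 ± 5.69).

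Of 18 genes of cell death and autophagy, 4 were higher in MATZ at 14 DAP, and 8 adjusted over the list alone (median −0.86, adjusted p = 0.00063): ccp1, ccp2, Atg8a and Atg8c (373 ± 5.67 against 123 ± 13.9). In the defense list 2 of 3 were higher in MATZ, and 2 adjusted over the list alone (median −1.47, adjusted p = 0.0465, adjusted p = 0.153 with an estimated correlation). Chitinase gene GRMZM2G453805 was at 473 ± 5.61 against 14.3 ± 6.89. This list call was lost without any 1 library of BETL 14 DAP, BETL 20 DAP, MATZ 8 DAP or MATZ 14 DAP, with 0.0994 without MATZ 14 DAP replicate 2. Nitrate transporter gene NRT1.2 was at 97.3 ± 30.5 against 5.55 ± 1.48 and the gibberellin synthesis gene d3 at 87.4 ± 3.73 against 4.15 ± 0.7898. Levels of acco20 were 215 ± 42.6 against 22.4 ± 4.26, and those of the homeobox gene kn1 26.1 ± 2.495 against 0 in both BETL libraries. The alcohol dehydrogenase gene adh2 was higher in MATZ (306 ± 33.1 against 42.7 ± 13.6). Its relative adh1 was higher in BETL (188 ± 13.8 against 82.04 ± 16.1; adjusted p = 0.0148, but up to 0.0711 without BETL 14 DAP replicate 2 or MATZ 14 DAP replicate 1).

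Zein genes, made in the starchy endosperm, were also higher in MATZ than in BETL at 14 DAP. Of 24, the alpha zein genes z1A1_3 (458 ± 63.5 against 111 ± 20.6) and z1A2_1 (450.1 ± 84.6 against 89.2 ± 26.1) passed the test over all genes. Adjusted over the list alone 10 passed (median −2.06, adjusted p = 5.99e-09). The list summed to 11534 ± 247 FPKM in MATZ and 4386 ± 88.6 in BETL (SD, n = 2). The gamma zein genes gz27 and gz16 stood at 1066 ± 25.01 and 2323 ± 12.5 in MATZ and 606 ± 57.9 and 765 ± 131 in BETL. Neither gamma zein gene passed the test at this age.

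By limma, 2180 genes differed at 14 DAP, 1120 higher and 1060 lower in BETL (1018 and 769 by at least 4-fold), with a median over all genes of 0.00. Log2 differences were 2.79 ± 0.29 for betl-9 (adjusted p = 0.0006), −2.84 ± 0.17 for pip2b (adjusted p = 3.38e-05) and −2.92 ± 0.19 for MADS4 (adjusted p = 4.18e-05). The balance depended on the setting: 1075 higher and 842 lower with median-of-ratios scaling (median 0.11), 995 and 1026 with quantile normalization, 589 and 1035 among genes with mean FPKM of at least 20 and 777 and 1026 without BETL 14 DAP replicate 2. The count was 1053 without BETL 14 DAP replicate 1, and 1401 and 966 without MATZ 14 DAP replicate 1 and 2.

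**Figure D3:**
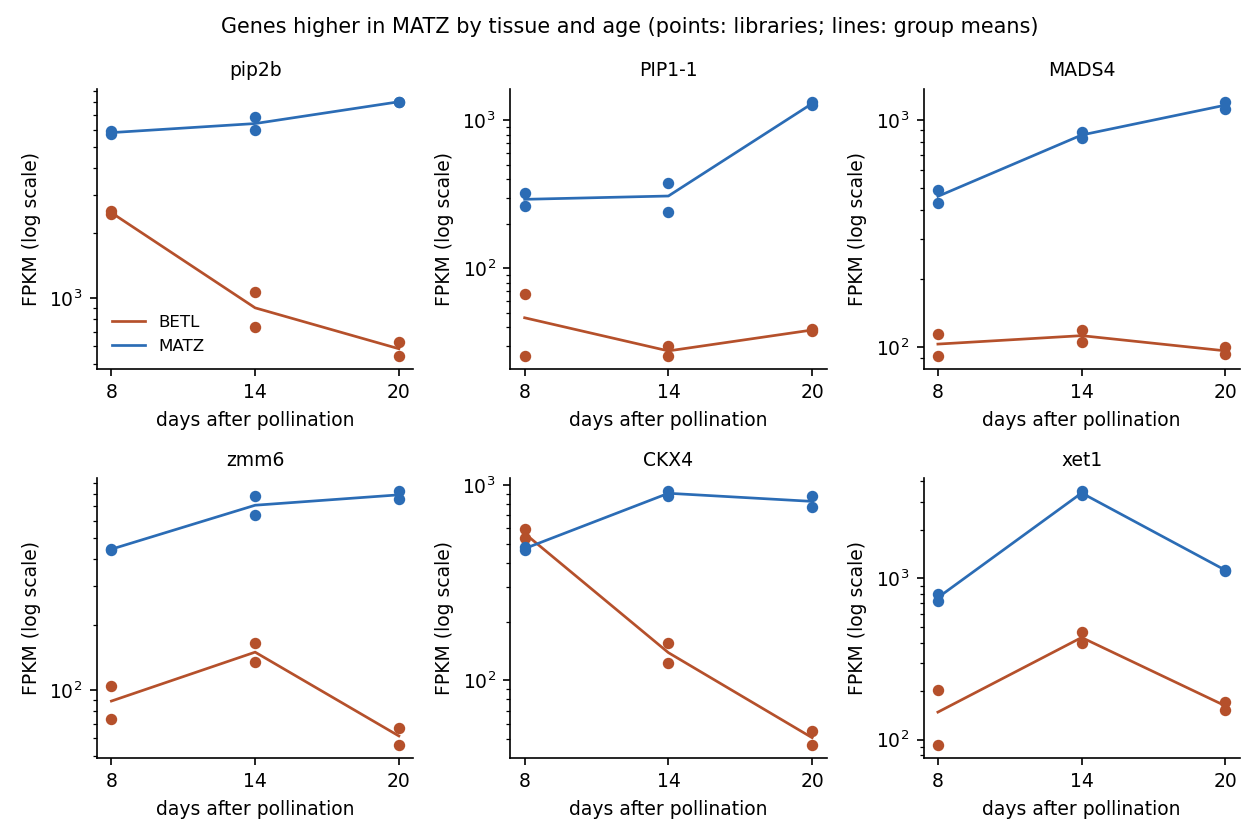
FPKM (log axis) of pip2b, PIP1-1, MADS4, zmm6, CKX4 and xet1 in BETL and MATZ against age in DAP; points are libraries and lines join the group means. At 14 and 20 DAP each gene was higher in MATZ under each scaling tried, and CKX4 stood at 564 ± 41.3 in BETL and 472 ± 11.97 in MATZ at 8 DAP.

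At 20 DAP the question was which differences were present late in filling. Basal endosperm transcripts were again far more abundant in BETL, betl3 at 36767 ± 2881 FPKM against 4828 ± 414 in MATZ (SD, n = 2) and betl-9 at 25113 ± 1147 against 2131 ± 321. Another marker, betl4 (GRMZM2G073290; chromosome 4, 208847826 to 208848375), was at 6478 ± 548 against 1029 ± 57.4. The maternally expressed gene MEG1 (GRMZM2G354335; chromosome 7, 13065608 to 13066906) was at 473 ± 29.7 in BETL and at 16.9 and 0 in the 2 MATZ libraries. Higher in MATZ was pip2b at 8058 ± 7.38 against 585 ± 60.4 (13.8-fold), with PIP1-1 at 1296 ± 53.7 against 38.4 ± 1.19 (33.8-fold). The auxin efflux gene PIN1a (GRMZM2G098643; chromosome 9, 3650766 to 3654174) was at 399.9 ± 91.1 against 30.3 ± 1.71.

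Of the BETL and basal endosperm list, 10 of 15 were higher in BETL at 20 DAP, and 12 adjusted over the list alone (median 2.93, adjusted p = 2.61e-11). Genes of the embryo and its surrounding endosperm had 4 of 14 higher, and 6 adjusted over the list alone (median 1.73, adjusted p = 0.00113). They were oleosin4, esr2 at 287 ± 8.203 against 30.9 ± 22.7, esr-6 at 174 ± 4.44 against 6.82 and 0 in the MATZ libraries and glb3 at 284 ± 17.1 against 42.2 ± 4.98. The ramosa gene ra3, which encodes a trehalose phosphate phosphatase, was at 222 ± 16.9 against 6.96 ± 5.52, and adh1 at 314 ± 41.01 against 60.1 ± 10.8. Starch synthesis genes were called as a list (2 of 15 higher in BETL, ae1 and bt1, 3 adjusted over the list alone, median 1.13, adjusted p = 0.0232). The list had adjusted p = 0.169 with an estimated correlation, and 0.0506 without MATZ 20 DAP replicate 1. The starch branching gene ae1 (GRMZM2G032628) was at 45.9 ± 11.4 in BETL and 4.42 ± 2.38 in MATZ (adjusted p = 0.0191, but up to 0.143 without BETL 20 DAP replicate 1 or 2 or MATZ 20 DAP replicate 2). Zeins were called higher in BETL as a list (median 0.65, adjusted p = 0.0159, adjusted p = 0.293 with an estimated correlation). That call was lost without BETL 20 DAP replicate 1 or MATZ 20 DAP replicate 1 (up to 0.0594). By limma 0 of the 24 zeins passed, over all genes or adjusted over the list alone, and 3 were at unadjusted p under 0.05.

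MATZ was higher for 13 of 28 MADS-box genes at 20 DAP and BETL for 1, MADS11 (17 and 1 adjusted over the list alone, median −3.14, adjusted p = 1.01e-09). Those in MATZ included MADS4 (1162 ± 57.8 against 96.6 ± 4.904), zag2 (596 ± 5.57 against 52.8 ± 8.04) and zmm6 (791 ± 46.9 against 61.6 ± 8.05). Aquaporins had 9 of 23 higher in MATZ, and 14 adjusted over the list alone (median −2.49, adjusted p = 1.41e-07), with pip2e at 503 ± 31.9 against 48.8 ± 8.996. Cytokinin genes had 9 of 23 higher in MATZ and 1, cko1, in BETL (11 and 1 adjusted over the list alone, median −1.74, adjusted p = 0.000174), with CKX4 at 823 ± 75.5 against 50.9 ± 6.03. Of 10 lignin genes, 4 were higher in MATZ, and 6 adjusted over the list alone (median −2.21, adjusted p = 0.000227). Beside both laccase genes these were BM1, a cinnamyl alcohol dehydrogenase gene, at 77.99 ± 22.6 against 2.43 ± 1.75, and pal3 at 58.9 ± 14.2 against 4.92 ± 1.17.

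Cell wall genes had 7 of 19 higher in MATZ at 20 DAP (9 with 2 the other way adjusted over the list alone, median −1.54, adjusted p = 0.0134, adjusted p = 0.188 with an estimated correlation). Of these xet1 was at 1125 ± 15.8 against 162 ± 12.1 and expB6 at 68.2 ± 17.7 against 5.57 ± 0.979. Cytosolic ribosomal protein genes had 7 of 29 higher in MATZ, and 11 adjusted over the list alone (median −0.98, adjusted p = 0.000126). That call had adjusted p = 0.0776 with an estimated correlation and 0.184 with quantile normalization. Gibberellin genes had 1 of 4 higher in MATZ, d3, and 3 adjusted over the list alone (median −2.02, adjusted p = 0.0267, adjusted p = 0.143 with an estimated correlation). This call was lost without BETL 20 DAP replicate 1 or either MATZ 20 DAP library (up to 0.0594). Single genes higher in MATZ were the phytosulfokine precursor gene PSK4 (264 ± 12.8 against 7.78 and 0 in the BETL libraries), the benzoxazinoid synthesis gene BX3 (34.2 ± 1.598 against 0 in both) and NRT1.2 (66.2 ± 0.627 against 1.01 ± 0.109). Others were the metal transporter gene ZIP4 (91.6 ± 1.26 against 7.61 ± 4.204), the kinase gene SnRK2.5 (68.4 ± 19.1 against 8.77 ± 1.24) and the small heat shock gene hsp18f (289 ± 78.2 against 39.5 ± 11.5).

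By limma, 2567 genes differed at 20 DAP, 1023 higher and 1544 lower in BETL (860 and 1168 by at least 4-fold), with a median over all genes of 0.00. Log2 differences were 2.93 ± 0.35 for betl3 (adjusted p = 0.000702), −3.79 ± 0.17 for pip2b (adjusted p = 3.43e-06) and −5.04 ± 0.40 for PIP1-1 (adjusted p = 7.24e-05). The split was 1126 higher and 989 lower with median-of-ratios scaling (median 0.19) and 1517 and 1316 with only the groups compared. The count was 1124 and 1104 without BETL 20 DAP replicate 1 and 2, and 1189 without MATZ 20 DAP replicate 2.

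The 3 tissue comparisons share no library but share 1 spread per gene, so genes of small spread are more easily called in each. The number given by independent lists is thus no null value. Higher in BETL at both 8 and 14 DAP were 294 genes (24.2 from independent lists), at 14 and 20 DAP 459 (47.3) and at 8 and 20 DAP 262 (22.1). Higher in MATZ were 319 (56.3), 665 (67.6) and 400 (81.9). At each of the 3 ages 211 genes were called higher in BETL, mn1, betl3, betl-9, bap2 and esr2 among them. Called higher in MATZ at each age were 244, pip2b, PIP1-1, MADS4, zmm6, acco20 and xet1 among them, and 52 genes were called in opposite directions at 2 ages.

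The change in BETL from 8 to 14 DAP was tested to follow the transfer layer into the main filling stage. Storage protein transcripts rose: the zein gene gz16 (GRMZM2G060429; chromosome 2, 183342461 to 183343536) went from 25.7 ± 20.9 to 765 ± 131 FPKM (SD, n = 2). The level of gz27 went from 28.7 ± 4.23 to 606 ± 57.9 and that of the delta zein gene dzs18 from 11.9 ± 0.514 to 516 ± 159. The cell wall invertase gene mn1 fell from 6738 ± 689 to 3179 ± 616 and pip2b from 2481 ± 55.2 to 903 ± 237. Laccase-13 (GRMZM5G814718; chromosome 1, 46411401 to 46414414) fell from 451 ± 79.8 to 9.63 ± 5.69.

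Of 24 zein genes, 17 rose in BETL by 14 DAP, and 18 adjusted over the list alone (median 4.82, adjusted p = 2.85e-12, adjusted p = 0.076 with an estimated correlation). The list summed to 79.2 ± 6.89 FPKM at 8 DAP and 4386 ± 88.6 at 14 DAP. Members listed at 0 in both 8 DAP libraries were bz15 (1573 ± 307 at 14 DAP) and the alpha zein genes z1A1_3 (111 ± 20.6), z1A2_1 (89.2 ± 26.1) and z1C1_7 (68.9 ± 42.2). Of 15 starch synthesis genes, 5 rose, and 6 with 1 falling adjusted over the list alone (median 2.0, adjusted p = 0.0485, adjusted p = 0.245 with an estimated correlation). Their call was lost without any 1 library except those of MATZ 14 DAP (0.154 without BETL 14 DAP replicate 2) and had 0.0811 with quantile normalization. The granule-bound starch synthase gene wx1 and the ADP-glucose pyrophosphorylase gene sh2 were listed at 0 in both 8 DAP libraries and stood at 63.2 ± 18.1 and 19.6 ± 5.37 at 14 DAP. The amino acid permease gene aap1 rose from 2.603 ± 0.235 to 42.1 ± 3.15, the chitinase gene GRMZM2G005633 from 7.89 ± 1.495 to 105 ± 2.04, and ZCN11 from 0 in both libraries to 202 ± 22.8.

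The BETL and basal endosperm list had 1 of 15 rising, betl-9, and 3 falling, bap2, mn1 and ebe2, and 2 and 4 adjusted over the list alone. The median was −0.65 (adjusted p = 0.00207, adjusted p = 0.21 with an estimated correlation and 0.559 with quantile normalization). Its sum was 50353 ± 6578 FPKM at 8 DAP and 54446 ± 6728 at 14 DAP. Within it bap2 fell from 13024 ± 2367 to 4267 ± 1706 (adjusted p = 0.00793, but 0.0549 without BETL 14 DAP replicate 1), while betl10 stood at 5967 ± 667 and 6125 ± 827. The fall of mn1 had adjusted p = 0.00585, but 0.0682 with quantile normalization.

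Of 23 aquaporin genes, 5 fell, pip2b and pip2f among them, and 1, tip3a, rose in BETL by 14 DAP. Adjusted over the list alone these were 6 and 2 (median −0.01, adjusted p = 0.00115, adjusted p = 0.076 with an estimated correlation). Carry-over of MATZ tissue into the BETL pieces, which could change with age, was not tested. The aquaporin list summed to 3222 FPKM in BETL and 7062 in MATZ at 8 DAP, and to 1382 and 7935 at 14 DAP. The defense list, also higher in MATZ at 8 DAP, summed to 15.6 and 1390 then, and to 120 in BETL at 14 DAP. Of 10 lignin genes, 2 fell, and 2 adjusted over the list alone (median −0.07, adjusted p = 0.014, adjusted p = 0.11 with an estimated correlation), LAC1 from 94.9 ± 26.8 to 13.2 ± 7.05 besides Laccase-13. Of 23 cytokinin genes, 4 fell, and 4 with 1 rising adjusted over the list alone (adjusted p = 0.0143 for lower, adjusted p = 0.11 with an estimated correlation, 0.0661 without BETL 14 DAP replicate 2). Their median was 0.12 and their mean −0.23, and the median was −0.23 under median-of-ratios scaling and −0.64 under quantile normalization. CKX4 went from 564 ± 41.3 to 139 ± 22.99 and cko2 from 85.2 ± 11.6 to 6.78 ± 3.22, and cko1 and cko3 fell too. Ribosomal protein genes had 4 of 29 falling and 1, rps27, rising, and 5 and 1 adjusted over the list alone (median −0.09, adjusted p = 0.000106, adjusted p = 0.11 with an estimated correlation).

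Heat shock genes had 3 of 23 falling, and 4 with 1 rising adjusted over the list alone. The median was 0.00, −0.40 under median-of-ratios scaling, and the mean 0.04, and the list was called lower relative to all genes (adjusted p = 0.0247, adjusted p = 0.116 with an estimated correlation). Of 3 lipid transfer protein genes 1 fell, and 1 adjusted over the list alone: plt1, from 120.1 ± 28.1 to 20.2 ± 1.75 (median of the list −0.85, adjusted p = 0.0247, adjusted p = 0.187 with an estimated correlation). Both lists had 0.0505 with quantile normalization. The heat shock call was lost without BETL 8 DAP replicate 1 or BETL 14 DAP replicate 2 (up to 0.144), and the lipid transfer call without BETL 8 DAP replicate 1 or either BETL 14 DAP library (up to 0.259). The protease gene ccp1 fell from 1958 ± 312 to 379.7 ± 44.98, the heat shock factor gene Hsf12 from 178 ± 10.1 to 21.8 ± 5.93 and the potassium transporter gene HAK17 from 108 ± 23.4 to 4.07 ± 2.602.

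By limma, 2818 genes changed in BETL between 8 and 14 DAP, 2194 higher and 624 lower at 14 DAP (1837 and 387 by at least 4-fold). The median log2 change of all genes was 0.75, and the split was 1358 higher and 1013 lower with median-of-ratios scaling (median 0.44) and 911 and 1016 with quantile normalization (median −0.03). Log2 changes were 5.10 ± 0.48 for gz16 (adjusted p = 0.000346), −1.48 ± 0.17 for pip2b (adjusted p = 0.00115) and −5.51 ± 0.45 for Laccase-13 (adjusted p = 0.000167). The count was 1544 without BETL 8 DAP replicate 1, 1102 and 1748 without BETL 14 DAP replicate 1 and 2, and 1855 and 1871 without BETL 20 DAP replicate 1 and 2, which enter through the shared spread.

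Between 14 and 20 DAP BETL changed less, in a comparison that asked what the transfer layer gained or lost late in filling. The tubulin gene tua4 (GRMZM2G152466; chromosome 5, 9471280 to 9475018) rose from 519 ± 12.5 to 1289.5 ± 45.6 FPKM (SD, n = 2). The endosperm gene fl3 (GRMZM2G006585; chromosome 8, 52090731 to 52092148) fell from 187 ± 59.0 to 13.5 ± 1.68. The phytase gene PAPhy (GRMZM2G134054) fell from 284 ± 15.1 to 61.4 ± 3.27 and FIP1 (GRMZM2G046782) from 191 ± 33.7 to 27.7 ± 1.12. CKX4 fell from 139 ± 22.99 to 50.9 ± 6.03 (adjusted p = 0.0103, but 0.0605 without BETL 20 DAP replicate 2). The gene aba1, also named asr1, fell from 94.7 ± 1.26 to 11.9 ± 8.004 (adjusted p = 0.00882, but 0.074 without BETL 14 DAP replicate 1). Of 15 BETL markers limma called 0, with 5 at unadjusted p under 0.05 and 3 higher and 2 lower adjusted over the list alone: betl3 stood at 14082 ± 2192 and 36767 ± 2881, bap2 at 4267 ± 1706 and 1517 ± 181, and mn1 at 3179 ± 616 and 2162 ± 138.

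Each list called in BETL between 14 and 20 DAP lost its call with an estimated correlation. Zeins had 1 of 24 falling, and 4 adjusted over the list alone (median −0.67, adjusted p = 0.00557, adjusted p = 0.292 with an estimated correlation). Their call was lost without BETL 14 DAP replicate 2 (0.433) and without BETL 20 DAP replicate 2. The falling member was gz27, from 606 ± 57.9 to 142 ± 3.74 (adjusted p = 0.0242, 0.0582 with quantile normalization and lost without any 1 library of BETL 14 DAP, BETL 20 DAP or MATZ 14 DAP, up to 0.138). MADS-box genes had 1 of 28 falling, zmm6, and 3 with 1 rising adjusted over the list alone (median −0.63, adjusted p = 0.0355, adjusted p = 0.195 with an estimated correlation, 0.0691 with quantile normalization). They were lost without either BETL 14 DAP or MATZ 20 DAP library or BETL 20 DAP replicate 2, with 0.182 without BETL 14 DAP replicate 1. Cell wall genes had 1 of 19 falling, the expansin gene expB3, and 4 adjusted over the list alone (median −0.62, adjusted p = 0.00261, adjusted p = 0.195 with an estimated correlation; 0.123 without BETL 14 DAP replicate 2). Lignin genes had 0 of 10 called by limma, 4 at unadjusted p under 0.05 and 2 falling adjusted over the list alone (median −0.79, adjusted p = 0.00557, adjusted p = 0.195 with an estimated correlation; 0.123 without BETL 14 DAP replicate 2). Of 3 sucrose synthase genes, limma called 0, with 1 at unadjusted p under 0.05 and 1 falling adjusted over the list alone (median −1.56, adjusted p = 0.0299, adjusted p = 0.195 with an estimated correlation). This call was lost without either BETL 14 DAP library or BETL 20 DAP replicate 2, up to 0.123.

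By limma, 194 genes changed in BETL between 14 and 20 DAP, 67 higher and 127 lower at 20 DAP. The log2 change of tua4 was 1.31 ± 0.16 (adjusted p = 0.00626), that of fl3 −3.67 ± 0.43 (adjusted p = 0.00569) and that of PAPhy −2.19 ± 0.20 (adjusted p = 0.00208). The split turned, with 172 higher and 135 lower (307 in all) without BETL 14 DAP replicate 2, 84 and 59 without BETL 20 DAP replicate 1, 73 and 57 without BETL 20 DAP replicate 2, 201 and 149 (350) without MATZ 8 DAP replicate 1, 205 and 156 (361) without MATZ 8 DAP replicate 2, 200 and 129 without the 8 DAP libraries and 166 and 165 with a pseudocount of 0.1. The count was 71 without BETL 14 DAP replicate 1 and 110 and 123 without MATZ 14 DAP replicate 1 and 2, each with more lower.

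The change in MATZ from 8 to 14 DAP was tested to follow the maternal side over the same interval. The MATZ pieces may also hold endosperm tissue, so changes of endosperm genes need not be those of the maternal zone. Zein transcripts rose steeply: gz16 went from 21.5 ± 6.76 to 2323 ± 12.5 FPKM (SD, n = 2) and gz27 from 7.14 ± 3.54 to 1066 ± 25.01. For dzs18 (GRMZM2G100018; chromosome 6, 121390345 to 121391179) the step was from 8.59 ± 1.89 to 1445 ± 4.33. Basal endosperm genes rose as well, betl3 from 378 ± 239 to 1709.9 ± 105 and betl-9 from 191 ± 73.7 to 2004 ± 322. The cell wall gene xet1 (GRMZM2G026980; chromosome 5, 53906406 to 53907982) rose from 761 ± 56.02 to 3391 ± 142, while mn1 fell from 1114 ± 60.2 to 511 ± 67.2.

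Of 24 zeins, 19 rose in MATZ, and 21 adjusted over the list alone (median 7.01, adjusted p = 1.72e-30), and the list summed to 62.7 ± 18.8 FPKM at 8 DAP and 11534 ± 247 at 14 DAP. The alpha zein genes z1A1_3, z1A2_1 and z1C2 were at 0 in both 8 DAP libraries and at 458 ± 63.5, 450.1 ± 84.6 and 451 ± 82.8 at 14 DAP. Of the 15 BETL and basal endosperm genes, 5 rose (betl-9, betl3, betl10, betl4 and betl1c) and 1 fell (mn1). Adjusted over the list alone these were 6 and 1 (median 1.17, adjusted p = 0.0105, adjusted p = 0.25 with an estimated correlation, 0.0812 without MATZ 14 DAP replicate 1). Of 14 embryo and embryo surrounding genes, 4 rose, and 5 adjusted over the list alone (median 1.25, adjusted p = 0.0105, adjusted p = 0.16 with an estimated correlation). They were lost without MATZ 8 DAP replicate 1 or MATZ 14 DAP replicate 2, up to 0.0676. Besides ole1 and esr1, esr2 went from 8.45 ± 3.98 to 145 ± 2.94 and glb3 from 0 in both libraries to 93.8 ± 2.82. Of 15 starch synthesis genes 3 rose, and 5 adjusted over the list alone, and the list was not called (median 0.98, adjusted p = 0.0807). Besides sh2, wx1 rose from 4.49 ± 1.29 to 55.4 ± 13.3 and bt1 from 0 in both libraries to 38.2 ± 28.8.

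Of 3 sucrose synthase genes, 2 rose in MATZ by 14 DAP, and 2 adjusted over the list alone (median 2.87, adjusted p = 0.0373, adjusted p = 0.16 with an estimated correlation). The list was lost without MATZ 8 DAP replicate 1 or MATZ 14 DAP replicate 2, up to 0.155. Besides sh1, sus1 rose from 1.82 ± 0.7396 to 19.4 ± 3.99. MADS-box genes had 1 of 28 rising, MADS4, and 4 adjusted over the list alone (median 0.79, adjusted p = 0.0448, adjusted p = 0.16 with an estimated correlation, 0.122 with median-of-ratios scaling). They were lost without any 1 MATZ library, with 0.155 without MATZ 14 DAP replicate 2. Cell death and autophagy genes had 1 of 18 rising, Atg8c, from 133 ± 1.68 to 373 ± 5.67, and 3 adjusted over the list alone. Their median was 1.15 (adjusted p = 0.0468, adjusted p = 0.16 with an estimated correlation, 0.185 with median-of-ratios scaling and 0.0829 with quantile normalization). Their call was lost without any 1 library except those of BETL 14 DAP and MATZ 8 DAP replicate 1, with 0.142 without MATZ 8 DAP replicate 2. Ribosomal protein genes had 3 of 29 falling, and 9 adjusted over the list alone (median −0.31, adjusted p = 0.000553, adjusted p = 0.16 with an estimated correlation). Chitinase gene GRMZM2G005633 rose from 36.6 ± 8.72 to 296 ± 61.6. The histone gene his2b5 fell from 127 ± 44.8 to 5.31 and 0 in the 14 DAP libraries, the lipid transfer gene plt1 from 195 ± 66.6 to 15.01 ± 7.32 and Hsf12 from 259.7 ± 62.9 to 67.3 ± 6.73. The aquaporin genes tip2b and pip2f fell from 26.5 ± 2.27 and 26.96 ± 9.59 to 0 in both libraries.

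By limma, 1352 genes changed in MATZ between 8 and 14 DAP, 752 higher and 600 lower at 14 DAP (576 and 426 by at least 4-fold). Of the 752, 108 (14.4%) were also called higher in BETL at 14 DAP, against 1120 of all 24213 tested genes. The median log2 change of all genes was 0.14. The split of 752 and 600 became 464 higher and 812 lower with median-of-ratios scaling (median 0.00). With quantile normalization it was 498 and 630 (median 0.10). Log2 changes were 6.72 ± 0.48 for gz16 (adjusted p = 8.05e-05), 2.33 ± 0.35 for betl3 (adjusted p = 0.00502) and 2.16 ± 0.30 for xet1 (adjusted p = 0.00373). The count was 776 and 516 without MATZ 14 DAP replicate 1 and 2.

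**Figure D4:**
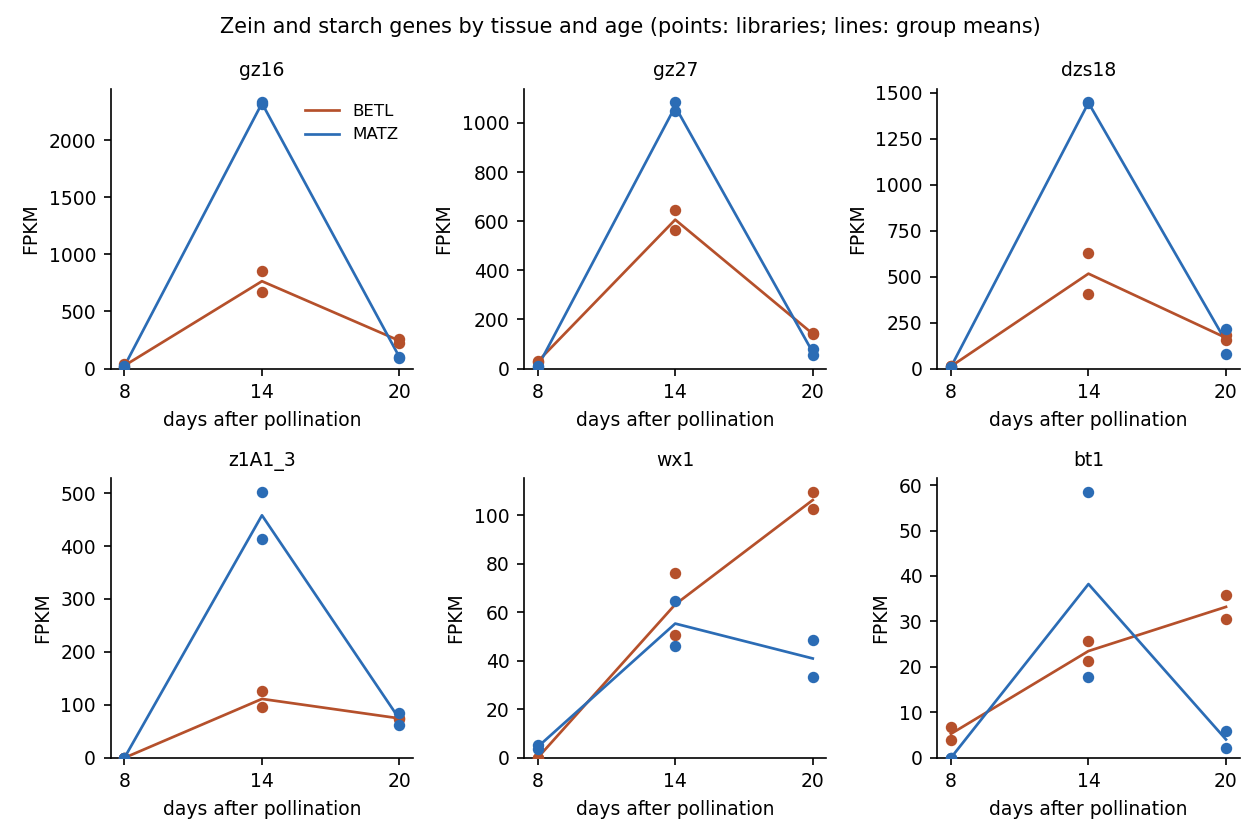
FPKM (linear axis) of the zein genes gz16, gz27, dzs18 and z1A1_3 and the starch genes wx1 and bt1 in BETL and MATZ against age in DAP; points are libraries and lines join the group means. In MATZ gz16 stood at 21.5 ± 6.76, 2323 ± 12.5 and 99.4 ± 3.696 at 8, 14 and 20 DAP, and the rise and fall of the zein list held under each scaling tried.

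Between 14 and 20 DAP the MATZ comparison asked what the MATZ pieces gained or lost as filling went on, and their zein transcripts fell. Whether these zeins came from the maternal zone or from carried endosperm could not be told apart. The level of gz16 went from 2323 ± 12.5 to 99.4 ± 3.696 FPKM (SD, n = 2) and that of gz27 from 1066 ± 25.01 to 66.5 ± 17.97. The chitinase gene GRMZM2G453805 went from 473 ± 5.61 to 2.81 and 0 in the 20 DAP libraries, and fl3 from 185 ± 68.96 to 0 in both.

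Of 24 zeins, 11 fell in MATZ by 20 DAP, and 19 adjusted over the list alone (median −3.40, adjusted p = 1.71e-28), and the list sum was 1031 ± 245 FPKM at 20 DAP. The delta zein gene dzs18 fell from 1445 ± 4.33 to 147 ± 99.4 (adjusted p = 0.00667, but 0.0501 without MATZ 14 DAP replicate 2). The sucrose synthase gene sh1 went from 40.3 ± 6.79 to 0 and 0.9996 in the 20 DAP libraries (adjusted p = 0.0171, lost without either MATZ 14 DAP library or MATZ 20 DAP replicate 1, up to 0.0798). Of 15 BETL markers limma called 0, with 7 at unadjusted p under 0.05 and 2 higher and 3 lower adjusted over the list alone, with betl3 at 1709.9 ± 105 and 4828 ± 414 and betl-9 at 2004 ± 322 and 2131 ± 321.

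Of 23 aquaporin genes, 2, PIP1-1 and tip3b, rose in MATZ by 20 DAP, and 4 adjusted over the list alone (median 1.03, adjusted p = 0.0187, adjusted p = 0.133 with an estimated correlation). They were lost without MATZ 14 DAP replicate 1 or MATZ 20 DAP replicate 2, up to 0.161. PIP1-1 went from 308 ± 93.5 to 1296 ± 53.7 (adjusted p = 0.0342, lost without any 1 library except those of BETL 8 DAP, up to 0.142). The level of pip2b was 6395 ± 613 at 14 DAP and 8058 ± 7.38 at 20 DAP, and that of MADS4 859 ± 42.05 and 1162 ± 57.8, without passing the test.

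By limma, 356 genes changed in MATZ between 14 and 20 DAP, 187 higher and 169 lower at 20 DAP, and the split was 135 and 192 with quantile normalization and 107 and 145 with median-of-ratios scaling. The log2 change of gz16 was −4.53 ± 0.48 (adjusted p = 0.00276) and that of the chitinase gene GRMZM2G453805 −7.92 ± 0.74 (adjusted p = 0.00169). The count was 203 and 201 without BETL 20 DAP replicate 1 and 2, 115 without MATZ 14 DAP replicate 2 and 136 without MATZ 20 DAP replicate 2. The BETL and MATZ changes over one interval share no library but do share the spread of each gene, so numbers from independent lists are again no null value. From 8 to 14 DAP 344 genes rose in both (68.1 from independent lists) and 151 fell in both (15.5), zeins and wx1 among the first and mn1, plt1 and Hsf12 among the second. From 14 to 20 DAP 43 fell in both (0.886), fl3, gz27, PAPhy and FIP1 among them, and 2, GRMZM2G010762 and GRMZM2G079547, rose in both (0.517).

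**Figure D5:**
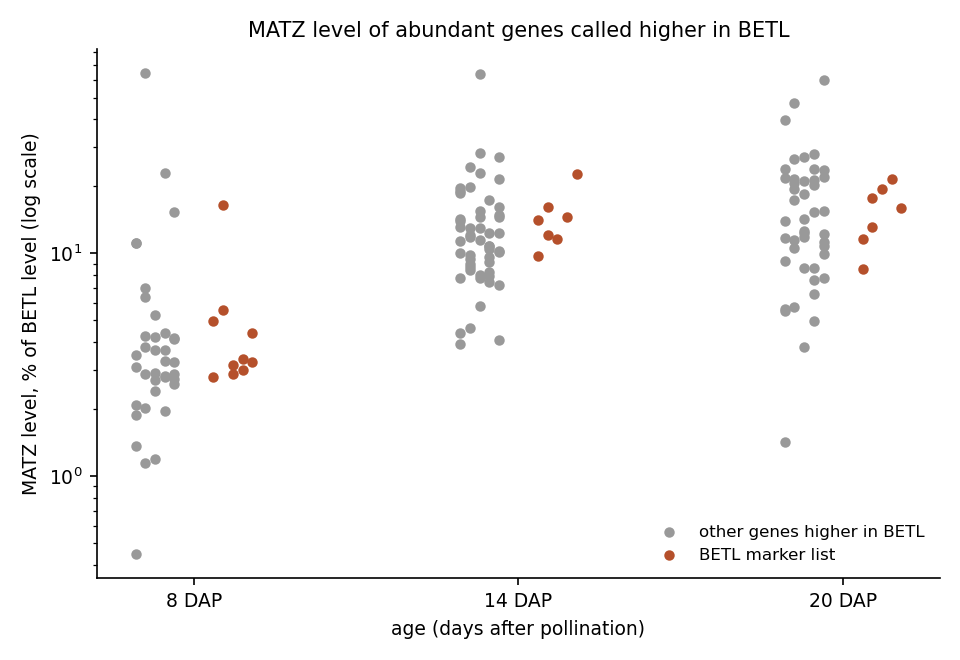
MATZ level as a percent of the BETL level (log axis) for genes called higher in BETL with at least 1000 FPKM there, at 8, 14 and 20 DAP, with 1 point per gene and the basal endosperm list set apart from other genes. The median of the list's genes among these was 3.29% at 8 DAP (10 genes), 14.1% at 14 DAP (7) and 15.9% at 20 DAP (7).

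Whether a change with age differed between the tissues was tested directly as a difference of changes. From 8 to 14 DAP fl3 went from 604 ± 55.9 to 187 ± 59.0 FPKM in BETL and from 7.86 ± 3.87 to 185 ± 68.96 in MATZ (SD, n = 2). BURP7 went from 9998 ± 1532 to 4941 ± 982 in BETL and from 44.8 ± 26.7 to 366 ± 48.2 in MATZ. The differences were −6.13 ± 0.61 log2 for fl3 (adjusted p = 0.00626) and −4.15 ± 0.48 for BURP7 (adjusted p = 0.00885). A larger share of endosperm tissue in the MATZ pieces at 14 DAP would also make such differences more negative. The test cannot tell this from a change within the tissues. The embryo surrounding region gene esr1 went from 134 ± 32.9 to 19.1 ± 11.6 in BETL and from 0 in both libraries to 14.3 ± 5.28 in MATZ. Its difference had adjusted p = 0.0194, but up to 0.0686 without BETL 8 DAP replicate 1 or MATZ 14 DAP replicate 2.

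The BETL and basal endosperm list moved lower in BETL than in MATZ from 8 to 14 DAP, with 4 of 15 members lower (betl-9, betl10, betl4 and bap2). Adjusted over the list alone 6 were lower (median difference −1.84, adjusted p = 1.51e-09, adjusted p = 0.0861 with an estimated correlation). Zeins had 1 of 24 lower, gz27, and 6 with 1 higher adjusted over the list alone (median −2.15, adjusted p = 3.27e-10, adjusted p = 0.0861 with an estimated correlation). Cell death and autophagy genes had 1 of 18 lower, ccp1, and 3 adjusted over the list alone (median −0.32, adjusted p = 0.0167, adjusted p = 0.112 with an estimated correlation). Of MADS-box genes limma called 0 of 28, with 6 at unadjusted p under 0.05 and 2 lower adjusted over the list alone (median −0.02, adjusted p = 0.0226, adjusted p = 0.112 with an estimated correlation). Both of the last lists were lost without BETL 8 DAP replicate 1, BETL 14 DAP replicate 2 or MATZ 14 DAP replicate 2, up to 0.107 for cell death and 0.168 for MADS-box genes. They had 0.0579 and 0.0649 with quantile normalization.

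By limma, 307 genes differed in their change from 8 to 14 DAP, 170 changing more towards higher values in BETL and 137 in MATZ. The median difference of all genes was 0.54, and the split was 179 and 180 with median-of-ratios scaling (median 0.48) and 88 and 124 with quantile normalization (median 0.04). It turned to 42 and 87 with the replicate block, and was 704 and 248 with a pseudocount of 0.1 and 130 and 34 without the mean trend. The count was 88 without BETL 8 DAP replicate 1, 144 and 500 without BETL 14 DAP replicate 1 and 2, and 148 and 162 without BETL 20 DAP replicate 1 and 2. It was 797 and 692 without MATZ 8 DAP replicate 1 and 2, 157 and 68 without MATZ 14 DAP replicate 1 and 2 and 202 without MATZ 20 DAP replicate 1.

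From 14 to 20 DAP the zein list changed by different amounts in BETL and MATZ: its sum went from 4386 ± 88.6 to 1525 ± 36.2 FPKM in BETL and from 11534 ± 247 to 1031 ± 245 in MATZ (SD, n = 2). The median difference of the 24 zeins was 2.73 (adjusted p = 4.38e-18). Limma called 0 of them over all genes, with 16 at unadjusted p under 0.05, and 15 higher adjusted over the list alone. Aquaporins (0 of 23 called, 8 at unadjusted p under 0.05, 0 adjusted over the list alone, median −1.03, adjusted p = 0.000318) had adjusted p = 0.0529 with an estimated correlation. Ribosomal protein genes (0 of 29 called, 10 at unadjusted p under 0.05, 4 lower adjusted over the list alone, median −0.98, adjusted p = 6.63e-07) had adjusted p = 0.064 with an estimated correlation. MADS-box genes (0 of 28, 6 at unadjusted p under 0.05, 1 lower adjusted over the list alone, median −0.73, adjusted p = 0.0497) had adjusted p = 0.161 with an estimated correlation, and 0.0648 with median-of-ratios scaling and 0.0921 with quantile normalization. They were lost without either MATZ 8 DAP or MATZ 20 DAP library, BETL 14 DAP replicate 1, BETL 20 DAP replicate 2 or MATZ 14 DAP replicate 1, up to 0.195. The defense list (0 of 3, 1 at unadjusted p under 0.05, 1 higher adjusted over the list alone, median 0.70, adjusted p = 0.0325) had adjusted p = 0.161 with an estimated correlation. It was lost without either library of BETL 14 DAP, MATZ 8 DAP or MATZ 14 DAP or MATZ 20 DAP replicate 1, up to 0.109.

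Over all genes limma called 9 for the difference from 14 to 20 DAP, 2 higher and 7 lower in BETL relative to MATZ, none of them with a descriptive name. The 2 were GRMZM2G122437 and GRMZM2G366392, and the 7 included GRMZM2G166141. The split was 2 and 0 with median-of-ratios scaling and 3 and 7 with quantile normalization, against a median of all genes of −0.14. The count rested on single libraries: it was 1 without either BETL 8 DAP library, 0 and 24 without BETL 14 DAP replicate 1 and 2, and 0 without either BETL 20 DAP library. It was 191 (109 higher) and 170 (99 higher) without MATZ 8 DAP replicate 1 and 2, 32 and 14 without MATZ 14 DAP replicate 1 and 2 and 2 without MATZ 20 DAP replicate 2. Where limma called 0, the genes at unadjusted p under 0.05 numbered 2100 without BETL 14 DAP replicate 1 and 1788 and 1780 without BETL 20 DAP replicate 1 and 2.

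Of the 28 lists tested, 12 were called in none of the 9 comparisons, and each is given in the comparison where its adjusted p was lowest. From 8 to 14 DAP in MATZ, limma called 0 of 7 photosynthesis genes (0 at unadjusted p under 0.05, 0 adjusted over the list alone, median −0.62, adjusted p = 0.115). Of 5 invertase genes 2 fell, mn1 and incw3 (2 adjusted over the list alone, median −0.12, adjusted p = 0.115). Of 3 sugar transporter genes 1 rose, sut1 (1 adjusted over the list alone, median 1.76, adjusted p = 0.115), and of 13 mineral transporter genes 1 fell, HAK1 (1 adjusted over the list alone, median −0.92, adjusted p = 0.115). From 14 to 20 DAP in MATZ, limma called 0 of 7 aleurone genes (0 at unadjusted p under 0.05, 0 adjusted over the list alone, median −0.85, adjusted p = 0.392). It called 0 of 4 proton pump genes (1 at unadjusted p under 0.05, 0 adjusted over the list alone, median −0.67, adjusted p = 0.13). From 8 to 14 DAP in BETL, 4 of 30 auxin genes rose (5 adjusted over the list alone, median 1.20, adjusted p = 0.374). So did 3 of 32 ethylene genes (3 adjusted over the list alone, median 0.85, adjusted p = 0.414). Of 7 flavonoid genes 1, a2, rose and 1, chi1, fell (1 and 1 adjusted over the list alone, median 0.00, mean 0.05, test lower, adjusted p = 0.365). From 14 to 20 DAP in BETL limma called 0 of 20 cell cycle genes (3 at unadjusted p under 0.05, 0 adjusted over the list alone, median −0.34, adjusted p = 0.366). At 8 DAP 1 of 22 abscisic acid genes, VP8, was higher in BETL (1 adjusted over the list alone, median −0.47, mean −0.16, test higher, adjusted p = 0.519). At 20 DAP 1 of 5 hypoxia genes was higher in BETL and 1 in MATZ, adh1 and adh2 (1 and 1 adjusted over the list alone, median 0.00, mean 0.07, test higher, adjusted p = 0.674).

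Camera compares a list with all other genes at a preset correlation of 0.01, and of 57 calls 19 held with an estimated correlation. Held were BETL markers, embryo and embryo surrounding genes and MADS-box genes at 8 DAP. At 14 DAP they were BETL markers, zeins, MADS-box, aquaporin, cytokinin, lignin and cell death genes, and at 20 DAP BETL markers, embryo and embryo surrounding, MADS-box, aquaporin, cytokinin and lignin genes. Held too were zeins in MATZ from 8 to 14 DAP, in MATZ from 14 to 20 DAP and in the difference of changes from 14 to 20 DAP. The fry test asks whether a list's genes move on balance one way, and its mixed form whether they change in either direction, and neither compares the list with other genes. For BETL markers at 8 DAP the adjusted p of fry was 6.34e-05. Camera compares the mean statistic of a list with that of all other genes, so its direction can differ from the sign of the median. Among others it was higher at 8 DAP for starch (median −0.25), invertase (−0.94), ethylene (−0.15) and ribosomal genes (−0.09), none of them called. The invertase median lay below that of all genes (−0.40).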

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

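Tests of carry-over between tissues and of zein classes and starch genes were chosen only after the results were seen. Those of the split of calls in BETL between 8 and 14 DAP were chosen after that split was seen. They were marked as set before their own values. Results stand here because a test of the difference between BETL and MATZ in a change with age (an interaction) passed its threshold.

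From 8 to 14 DAP 307 genes differed, and from 14 to 20 DAP 9. Many of the 307 had been called in the opposite direction between the tissues at 8 DAP, as given above. Named genes with a more positive change in BETL were CA (log2 difference 5.77), rws1 (3.95), bZIP116 (3.87), bHLH129 (3.77) and NAR2.2 (3.74). Those with a more negative change were esr1 (−6.74), fl3 (−6.13), leg1 (−5.56), tcrr-1 (−4.64), BURP7 (−4.15) and bap2 (−2.14). Of these, fl3 and BURP7 passed without each of the 12 libraries in turn. The others had adjusted p from 0.0686 (esr1, without MATZ 14 DAP replicate 2) to 0.119 (rws1 and bHLH129) in their least favourable fit; NAR2.2 lost its call without either library of BETL 8 DAP or MATZ 14 DAP or BETL 14 DAP replicate 1, and leg1 without either library of BETL 20 DAP or MATZ 14 DAP or replicate 1 of BETL 8 or 14 DAP. Calls held only without the libraries named here: CA without BETL 14 DAP replicate 2 or MATZ 8 DAP replicate 1, rws1 without replicate 1 of BETL or MATZ 8 DAP, bZIP116 without either MATZ 8 DAP library, bHLH129 without replicate 2 of BETL 14 DAP or MATZ 8 DAP (10 of 12 fits lost for each of these 4), tcrr-1 without BETL 14 DAP replicate 2 or either MATZ 20 DAP library (9 lost) and bap2 without BETL 14 DAP replicate 2 (11 lost). Camera, which is relative to all genes, called these lists for the difference. From 8 to 14 DAP (median of all genes 0.54) they were BETL markers (median −1.84), zeins (−2.15), MADS-box (−0.02, with 0 of 28 called by limma) and cell death genes (−0.32). From 14 to 20 DAP (median of all genes −0.14) they were zeins (2.73), MADS-box (−0.73), aquaporins (−1.03), defense (0.70) and ribosomal protein genes (−0.98). Of these 9 list calls zeins from 14 to 20 DAP alone held with an estimated correlation. The others then had adjusted p from 0.0529 to 0.161, as given above.

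BETL markers were present in MATZ, where from 8 to 14 DAP 5 of 15 rose, mn1 fell and 9 were not called (list adjusted p = 0.0105, adjusted p = 0.25 with an estimated correlation, 0.0812 without MATZ 14 DAP replicate 1); among the markers called higher in BETL with at least 1000 FPKM there, a set that differs with age, the median MATZ level was 3.29% of the BETL level at 8 DAP (10 markers), 14.1% at 14 DAP (7) and 15.9% at 20 DAP (7). Carry-over of BETL tissue into the MATZ pieces would bring all abundant BETL transcripts at a like share. Genes called higher in BETL with at least 1000 FPKM there were compared with the marker median. Within 2-fold of it lay 36 of 47 at 8 DAP, 52 of 59 at 14 DAP and 40 of 52 at 20 DAP. Under 0.25 of it lay 2.13% (1, BURP7), 0% and 3.85% (2), and over 4 times it 4, 1 and 0 genes. Against 1 uniform share as the whole source, 3 of these genes at 8 DAP, 5 at 14 DAP and 7 at 20 DAP, none of them markers, lay under 0.5 of the marker median in both MATZ libraries, among them BURP7 at 8 DAP (0.637% and 0.259%), dhar2 at 14 DAP (3.96% and 5.27%) and GRMZM2G406552 at 20 DAP (5.68% and 5.37%), and mn1 stood at 16.5% at 8 DAP, above the marker median. Some lay just under the cut in 1 library. GRMZM2G426158 stood at 0.645% and 1.73% at 8 DAP (marker medians 2.76% and 3.66%), and GRMZM2G158400 at 5.15% and 8.04% at 20 DAP (15.3% and 16.1%). How many genes sampling alone would put under the cut was not worked out. With most genes near 1 share, carry-over may account for much of the marker level, and for more if BETL parts were carried unequally (not tested). Expression of these genes in MATZ itself, changing with age, stays open as untested. A rise of the carried share from 8 to 14 DAP would by itself make the differences of changes more negative for BETL markers and BURP7. They therefore cannot tell carry-over from a change within the tissues.

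Zeins were higher in MATZ than in BETL at 14 DAP and fell in MATZ by 20 DAP. If 1 carried tissue gave the zeins of both BETL and MATZ, alpha zeins and other zeins would have the same MATZ to BETL ratio. Their median log2 ratios were 2.26 (15 genes) and 1.49 (5 genes), a difference of 0.77. Starchy endosperm carried into MATZ alone, with BETL holding zeins of its own, makes no such prediction. The difference therefore does not bear on it. The difference of their means was tested by a two-sided exact permutation over genes (p = 0.000838), where genes are not independent replicates. Splitting of reads between near-identical alpha zein genes would make their ratios less independent still. Carry-over and a difference of tissue cannot be told apart here. Starchy endosperm carried into MATZ at 14 and not at 20 DAP would lower starch genes as well, and 3 starch genes with at least 20 FPKM changed by a median of −2.05 (−2.84 to −0.43) against −3.47 for zeins, while over all 15 starch genes the median was −0.43 and limma called 0 (2 at unadjusted p under 0.05). The median of the 3 was as low as the test asked for, but the rule that 3 genes are too few to decide was set after the value was seen, so the test supports neither side, and a difference of the tissue or its age stays open as untested.

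Of the genes called in BETL between 8 and 14 DAP, 77.9% were higher at 14 DAP. With median-of-ratios scaling the share was 57.3%, as a scale difference between the libraries would give, but this scaling would also take out a real rise of many genes, so the value does not speak for either. Among genes with mean FPKM of at least 20 it was 68% and with the 10 most abundant genes of each library removed (44 genes) and the rest rescaled 67.8%, between the former values, so that zeros of low genes in shallow libraries and the share of a few transcripts cannot be told apart from a wider rise. A difference of age stays open as untested.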

How the results depend on the processing

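Library weights, a mean FPKM of at least 20 and a fit without the 8 DAP libraries were chosen after seeing the data; the other settings were planned. Counts of called genes not given here stayed within 1.5 times the reported count. With a pseudocount of 0.1 the count was 331 for BETL 20 against 14 DAP, 952 for the difference of changes from 8 to 14 DAP and 116 for that from 14 to 20 DAP, and with a pseudocount of 5 it was 622 for MATZ 20 against 14 DAP. With FPKM of at least 5 it was 128 for BETL 20 against 14 DAP, and with median-of-ratios scaling 2 for the difference from 14 to 20 DAP. Without the mean trend it was 48 for BETL 20 against 14 DAP and 164 for the difference from 8 to 14 DAP. With library weights (2.38 for BETL 20 DAP, 0.797 to 0.884 for the others) it was 3896 for the tissues at 20 DAP, 364 for BETL 20 against 14 DAP, and 101 and 14 for the differences. With mean FPKM of at least 20 the difference from 14 to 20 DAP had 40 genes, and without the 8 DAP libraries BETL 20 against 14 DAP had 329 and that difference 138. In these settings the cause was not tested. With only the groups compared, 2 residual degrees of freedom remained in a pairwise fit, and limma called 0 genes for the tissues at 8 DAP (4303 at unadjusted p under 0.05) and 14 DAP (4637), for BETL 14 against 8 DAP (5239) and 20 against 14 DAP (2958), and for MATZ 14 against 8 DAP (4155) and 20 against 14 DAP (2714), while the differences had 1 and 138. Leaving out 1 library gave 1029 to 1784 genes for the tissues at 8 DAP, 966 to 2327 at 14 DAP and 1104 to 2809 at 20 DAP, 1102 to 2837 and 71 to 361 for the steps in BETL, 516 to 1451 and 115 to 439 for the steps in MATZ, and 68 to 797 and 0 to 191 for the differences; the lone library left in a group was assumed to vary like the other groups. The replicate block gave 108 genes for BETL 20 against 14 DAP, 129 and 1 for the differences, and 1571, 1937, 2335, 2519, 1113 and 256 for the rest; replicate differences of 2 groups correlated across genes with r from −0.0168 to 0.0164, so the numbers gave no sign of pairing. Of 306 calls of named genes, 66 were lost with a pseudocount of 0.1, 66 without the trend, 32 with median-of-ratios scaling, 29 with quantile normalization, 29 with the block, 27 with weights and 260 with only the groups compared; 193 of the 363 calls of named genes and lists passed without each library in turn. Depth limits low genes most: with 94191 to 602344 inferred fragments, a listed 0 does not exclude a low level.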

Other observations

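Some of the most abundant transcripts had no descriptive name and were chosen after their values were seen; no test chosen for them was run beyond the comparisons above. At 8 DAP GRMZM2G166141 (chromosome 10, 101520598 to 101521474) was at 95701 ± 2416 FPKM in BETL and 93816 ± 20397 in MATZ (SD, n = 2), at 14 DAP at 369 ± 73.9 and 931 ± 177, and at 20 DAP at 38.4 ± 3.54 and 654 ± 132. GRMZM2G150091 (chromosome 7, 13208679 to 13209853) went from 35938 ± 148 through 1403 ± 49.3 to 69.9 ± 25.3 in BETL and from 53513 ± 6425 through 5469 ± 202 to 422 ± 59.6 in MATZ. GRMZM2G039538 was at 17284 ± 395 in BETL and 11546 ± 1585 in MATZ at 8 DAP and at 13.8 ± 3.84 and 35.6 ± 2.85 at 20 DAP. GRMZM2G136364 was at 9533 ± 240.3 and 9933 ± 1565 at 8 DAP, and at 20 DAP at 1.199 and 0 in the BETL libraries and 8.51 ± 0.0638 in MATZ. The log2 changes from 8 to 14 DAP in BETL and MATZ were −8.03 and −6.65 for GRMZM2G166141, −4.68 and −3.29 for GRMZM2G150091, −7.63 and −5.66 for GRMZM2G039538 and −7.62 and −6.02 for GRMZM2G136364, each called by limma.

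Other unnamed transcripts marked 1 tissue. GRMZM2G406552 (chromosome 4, 195759880 to 195760460) stood at 65866 ± 6373, 132183 ± 2437 and 212765 ± 19338 in BETL at 8, 14 and 20 DAP and at 1379.6 ± 563, 10247 ± 894 and 11749 ± 470.2 in MATZ, and GRMZM5G897740 at 4518 ± 217, 17856 ± 4086 and 32272 ± 2259.7 against 122 ± 25.5, 1758 ± 21.6 and 2448 ± 318. GRMZM2G107302 went from 24687 ± 564 to 2964 ± 231 in BETL, where it was higher than in MATZ at each age. In MATZ, GRMZM2G067315 (chromosome 1, 235909167 to 235910673) stood at 22227 ± 497, 11740.0 ± 8.52 and 3039 ± 145 against 785 ± 28.4, 769.6 ± 111 and 88.8 ± 8.94 in BETL. GRMZM2G031317 stood at 2499 ± 493, 7167 ± 1064 and 7806 ± 212 against 264 ± 5.08, 579 ± 101 and 314 ± 1.53, and GRMZM2G044174 at 6454 ± 1049 in MATZ and 306 ± 27.8 in BETL at 20 DAP. Each of these tissue differences was called by limma.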
